A study of Drosophila melanogaster with 3 samples.

How the data were processed

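Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster larvae at the wandering stage, late in the third instar, with males and females pooled. The flies were transgenic and expressed the product of the gene pipsqueak (psq) with green fluorescent protein at its C-terminal end. Chromatin was sheared by sonication and recovered with an antibody against the fluorescent protein. Per the labels, the series holds 1 group of 3 biological replicates. Their library fragment sizes were 200 to 300 bp in replicate 1, 175 to 275 bp in replicate 2 and 175 to 250 bp in replicate 3. There is no other condition, so no difference between groups was tested.

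The deposited files are lists of peaks with the positions of their summits. Peaks were called by the authors per replicate and on all replicates together, each time against 1 control alignment, the same for all replicates. These lists hold peaks together with background and served as input for the irreproducible discovery rate (IDR), by which the optimal list was thresholded. These steps are stated per the file listing deposited with the samples. All lists are given on the genome builds dm6 and dm3, per the labels. The peak caller, the aligner, their versions and the read filters are not given in the sources used here. Signal tracks and the control sample were not analysed here.

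Each peak carries a score, which is the authors' own value per peak, named as the signal value of the format per the deposited file listing, and it was used here only to rank and describe peaks within a list. The −log10 of the q value per peak was also deposited by the authors, but all 10138 optimal peaks tie at the list maximum of 4.32, so ranks were taken from the score. The other column used was the summit offset that the authors deposited for each peak, from which 1-based summit positions were computed. The optimal list was identical to the 10138 highest-scoring peaks of the list called on all replicates together. Read counts are not in these lists, so the depth of each sample is unknown, no interval that needs depth is given, and a region without a peak is only without a call. To set values from different replicates side by side, a peak's score in a replicate was divided by the median score of that replicate's 10138 highest-scoring peaks (relative score), and it is given as mean ± SD over replicates with a summit within 200 bp.

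Annotation and sequence were those of the dm6 assembly (Ensembl release 115 for genes and the NCBI RefSeq sequence of the assembly). All peaks lay inside the chromosome lengths of that assembly. The dm3 lists were used only for numbers of peaks and scores per chromosome, and no coordinate was converted. Transposable element annotations were left out, which left 18277 genes with 24111 distinct transcription start sites (TSSs), among them 13968 protein-coding genes. Genomic analyses used the 10105 optimal peaks on chromosome arms 2L, 2R, 3L, 3R, 4 and X. The remaining 33 were mitochondrial.

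Overlap between replicates was the share of the 10138 highest-scoring peaks of a replicate with a summit within 200 bp of such a peak in another. It was set against 1000 random draws of as many peaks from the full lists (permutation, 1-sided). Summits were assigned to the first matching class among promoter (within 500 bp of a TSS), 5′ UTR, coding sequence, 3′ UTR, other exon, intron and intergenic, and compared with 1000 random placements on the same arms (permutation, 2-sided). The X to autosome ratio of peak density has a 95% interval from 10000 resamples of blocks of 100 kb. A set of 11 short sequences fixed in advance were counted on either strand within 100 bp of each summit, and in 1 control window per peak from the same arm and class with GC content within 2 percentage points (Fisher's exact test, 2-sided). A gene counted as bound with a summit within 1000 bp of any of its TSSs, so a peak between neighbouring genes counts for both. For 29 gene lists the number bound was compared with 10000 random lists matched on 10 bins of gene length and on the number of TSSs (1, 2, or 3 and more; permutation, 2-sided). Benjamini-Hochberg adjustment was applied within each family of tests. These tests count peaks or genes, which are not independent replicates, and the spread between replicates is given beside them as SD. Of 759 listed gene names, 8 were matched through a synonym and 2 (pfk and ban) had no protein-coding gene of that name.

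The groups, tests, gene lists and alternatives were fixed before the data were examined, except where stated. The rule for named genes took the gene nearest to each of the 20 highest-scoring optimal peaks found in all 3 replicates, the 4 bound genes with the highest score near a TSS in each list that passed the test and up to 2 in each other list, and psq, Trl and the 8 homeotic genes in any case. Taken over all chromosomes, the first part gave 19 mitochondrial peaks and 1 nuclear peak, and it was therefore applied to the nuclear arms, a restriction chosen after seeing the data. Alternatives were other distances, windows, control regions and matching, the higher-scoring part of the optimal list (5052 peaks), and optimal peaks supported by both other replicates with each replicate left out in turn.

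The computations were tested on simulated data made on the same genome. Of 10000 simulated peaks with 60% shared between lists, 61.4% were found shared, the excess being chance neighbours. In 9995 simulated windows a GAGAG share of 46.2% was recovered as 46.2%, and with nothing planted the odds ratio was 0.961. Among 13968 genes all 20 planted lists were called, and 1.5% of 200 unplanted lists of long genes had an unadjusted p under 0.05 (permutation). Simulated binding was drawn gene by gene and rose with length, on which lists are matched. Lists with adjacent genes that share peaks were therefore not covered by this simulation. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.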

Results

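Binding of Psq was profiled in whole wandering larvae by ChIP-seq against its fluorescent tag. Psq is a nuclear protein with a BTB domain and Psq-type DNA-binding domains, known to bind GA-repeat DNA. The 3 biological replicates gave permissive lists of 28037, 28294 and 24291 peaks on dm6, and the authors' optimal list held 10138 peaks with a median width of 250 bp. Read depth is unknown for these lists. The design has a single group, so the comparisons it implies are those between replicates and those between bound sites and the rest of the genome.

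The replicates shared most of their strongest sites. Replicates 1 and 2 shared 71.4% of their 10138 highest-scoring peaks, replicates 1 and 3 shared 69.5%, and replicates 2 and 3 shared 71.7%. Random draws from the same permissive lists shared 21.8% to 23.9%, and the permutation p was 0.000999 for each pair, the smallest that 1000 draws can give. Over peaks matched between the full lists, Spearman's rho of the scores was 0.731, 0.723 and 0.741 in the same order, across peaks, which are not independent replicates. Of the optimal peaks, 5920 (58.4%) lay within 200 bp of a strong peak in all 3 replicates, 2478 in a pair of them, 1373 in a single replicate and 367 in none. Each replicate held 79.2% ± 1.7 (SD, n = 3) of the optimal peaks. Since the optimal list consists of peaks called on all replicates together, this support is not independent of the replicates. It depended on score, from 99.4% in the highest of 10 equal parts of the list to 6.51% in the lowest.

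**Figure D1:**
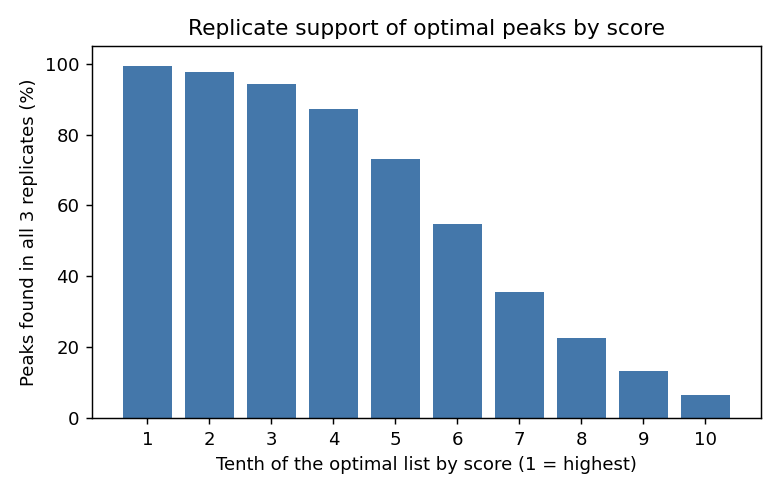
Bars give the percent of optimal peaks with a summit within 200 bp among the 10138 highest-scoring peaks of all 3 replicates (y axis), in 10 equal parts of the optimal list by score (x axis, 1 is the highest). The share falls from 99.4% to 6.51%.

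The strongest nuclear peak lay in psq itself, where extra DNA copies in these transgenic flies are not excluded. This peak (dm6 2R:10558619-10559191) lies in an intron 1076 bp from the nearest psq TSS, and its score was 7485 in the optimal list. Relative to the median score of each replicate's list, it was 41.1 ± 1.88 over the replicates (SD, n = 3). The 100 bp on each side of its summit held 4 occurrences of GAGAG and a GA run of 10 bp. The median score of all 72 peaks called in the psq span on the replicates together was at percentile 96.2 among 598 other genes with at least 10 such peaks. The next peaks were a pair in an intron of Smr (X:12735032-12735615 and X:12735728-12736514), a corepressor of nuclear receptors, with relative scores of 23.5 ± 0.972 and 22.6 ± 1.29 (SD, n = 3). Intergenic DNA 11134 bp from the nearest annotated TSS, that of CG14621, held the fourth (X:22432917-22433278), at 20.7 ± 5.23 (SD, n = 3). That window had no GAGAG and a GC content of 22.4%, and 29.2% of its words of 31 bases occur more than once in the genome, against 0 in the other 19 peaks.

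Genes of the ecdysone response, the steroid hormone response that drives metamorphosis, were among those at the 20 highest peaks. The promoter of EcR (2R:6131792-6132370), which encodes the ecdysone receptor, had a relative score of 16.3 ± 0.6 (SD, n = 3). Hr3, a nuclear receptor induced by ecdysone, had a promoter peak (2R:10227955-10228324) at 12.8 ± 1.22, and the zinc finger gene crol had peaks in its 5′ UTR (2L:11807530-11808320, 15.2 ± 2.35) and an intron (2L:11805959-11807387, 12.2 ± 5.45; SD, n = 3 each). Further peaks among the 20 lay in introns of other genes. Introns of upSET, a SET-domain protein, held peaks at 3L:14002697-14003176 (17.2 ± 0.324) and 3L:14004004-14004458 (14.7 ± 0.631), and introns of Tet (15.3 ± 1.35), Rga (14.1 ± 2.59) and MEP-1 (13.7 ± 1.85) held 1 each (SD, n = 3). A peak in an intron of brat (2L:19136202-19136795), nearest to the TSS of Polr1D, reached 17.0 ± 2.2, and an intron of Pepck2, a gluconeogenic enzyme, reached 14.5 ± 0.834 (SD, n = 3). The others were nearest to CG1910, CG31075, CG10543, dikar and CG32486, with relative scores from 12.7 to 17.0. Of the 20 peaks, 12 were intronic, 5 lay in promoters, 2 were intergenic and 1 lay in a 5′ UTR, and 16 had GAGAG within 100 bp of the summit.

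Peaks at psq were not limited to its highest one, and extra copies are not excluded for the others either. The gene's span (2R:10557888-10617280) with 1000 bp on each side held 46 optimal peaks, 11 of them within 1000 bp of a TSS. The strongest of those 11 lay 159 bp from a TSS, with a relative score of 5.67 ± 1.37 (SD, n = 3). Trl, which encodes the other well-known GA-repeat binding protein of the fly (GAGA factor), had 8 peaks in its span (3L:14747929-14761049) with 1000 bp on each side, the highest near a TSS in a promoter at 2.42 ± 0.32 (SD, n = 3).

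**Figure D2:**
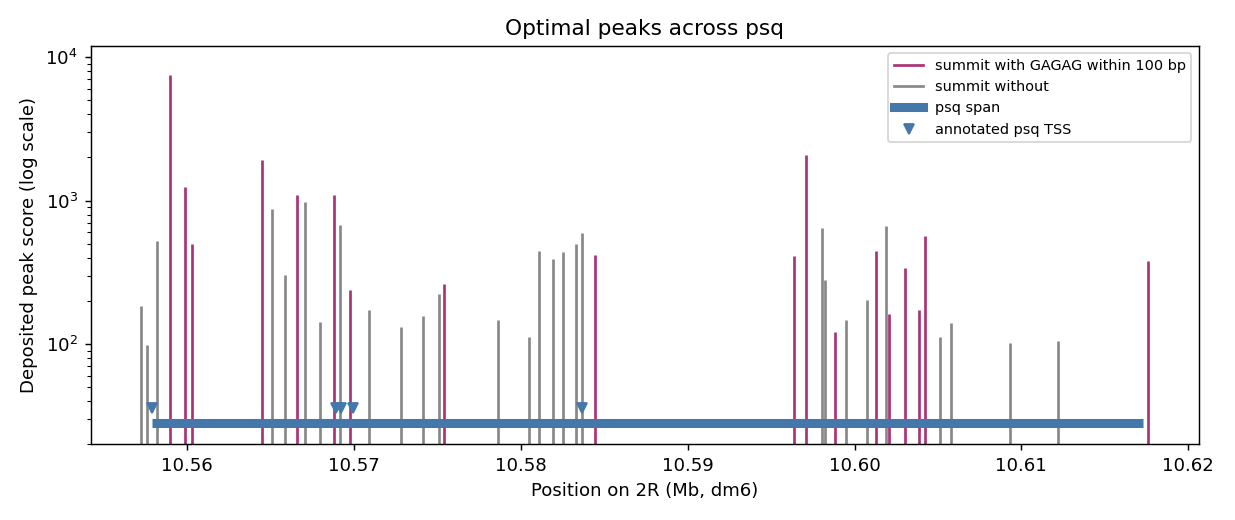
Map of psq on 2R (x axis, Mb of dm6), where each vertical line is an optimal peak at its summit with its deposited score on a log axis, coloured by whether GAGAG lies within 100 bp, the bar is the gene span and triangles are annotated TSSs. The highest line, at a score of 7485, lies just downstream of the first TSS.

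Promoters were the class most enriched in summits over random placement. Of the 10105 nuclear summits, 44.1% lay within 500 bp of a TSS, against 13.6% of randomly placed summits, a ratio of 3.25, which was 5.52 with promoters of 200 bp (34.0% against 6.17%). Over the replicates the share was 44.7% ± 0.42 (SD, n = 3). Summits in 5′ UTRs were also above random placement (1.68% against 0.784%). Coding sequence (0.91% against 13.7%), 3′ UTRs (0.901% against 4.41%) and intergenic DNA (13.02% against 27.3%) were below it. Adjusted p was 0.0028 in each of these classes by permutation, from the smallest p that the placements can give. The coding sequence ratio fell from 0.0664 to 0.0318 in the higher-scoring part of the list. Among optimal peaks supported by both other replicates it was 0.049 without replicate 1, 0.0419 without replicate 2 and 0.0499 without replicate 3. Introns held 38.4% of the summits against 39.4% (adjusted p = 0.0396, permutation), and with promoters narrowed to 200 bp the intron ratio turned from 0.975 to 1.03. With that narrower window introns held 42.8% of the summits, more than promoters did (34.0%). Other exons were not distinguishable from random placement (0.97% against 0.817%, adjusted p = 0.118, permutation).

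**Figure D3:**
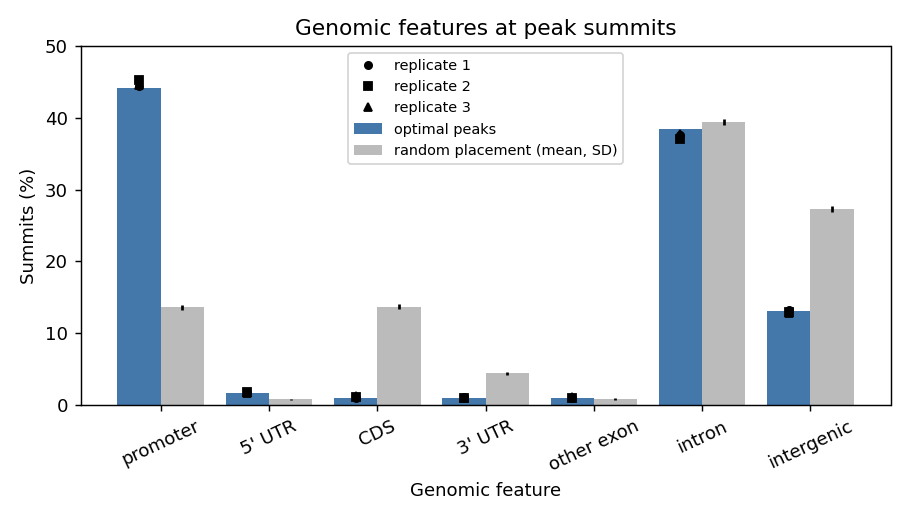
Percent of summits (y axis) in each class of genomic feature (x axis) for optimal peaks and the mean of random placements with its SD, with black symbols for the 10138 highest-scoring peaks of each replicate. Promoters hold 44.1% of optimal summits against 13.6% of placed ones.

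The large chromosome arms were bound at similar density. Peaks per Mb were 72.1 on 2L, 78.7 on 2R, 81.7 on 3L, 71.8 on 3R and 76.2 on X in the optimal list. Over the replicates these were 72.1 ± 0.595, 79.1 ± 0.713, 80.9 ± 0.73, 71.9 ± 1.08 and 76.3 ± 0.468 (SD, n = 3). The X to autosome ratio was 1.00 (95% block bootstrap interval 0.873 to 1.15). The larvae were pooled males and females, so X carried fewer copies than the autosomes. Chromosome 4 had 21.5 peaks per Mb (23.2 ± 2.27 over the replicates, SD, n = 3), and no optimal peak was called on Y.

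The GA word was concentrated at the summits. GAGAG occurred within 100 bp of 45.3% of summits and in 26.5% of matched control windows (odds ratio 2.29, adjusted p = 3.09e-170, Fisher's exact test). Over the replicates the shares were 44.6% ± 0.748 and 26.1% ± 0.638 (SD, n = 3). The longer repeat GAGAGAGA was rarer but more selective, at 8.65% against 1.79% (odds ratio 5.19, adjusted p = 4.34e-114, Fisher's exact test). With the list split by score into 10 equal parts, 60.7% had GAGAG in the highest part and 34.1% in the lowest, while control windows stayed between 23.9% and 28.3%. Occurrences per kb and peak were highest, at 6.44, in the 50 bp before the summit. All classes with over 100 peaks had a higher share than their controls, from 40.3% against 27.1% in intergenic DNA to 64.1% against 31.2% in 5′ UTRs.

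**Figure D4:**
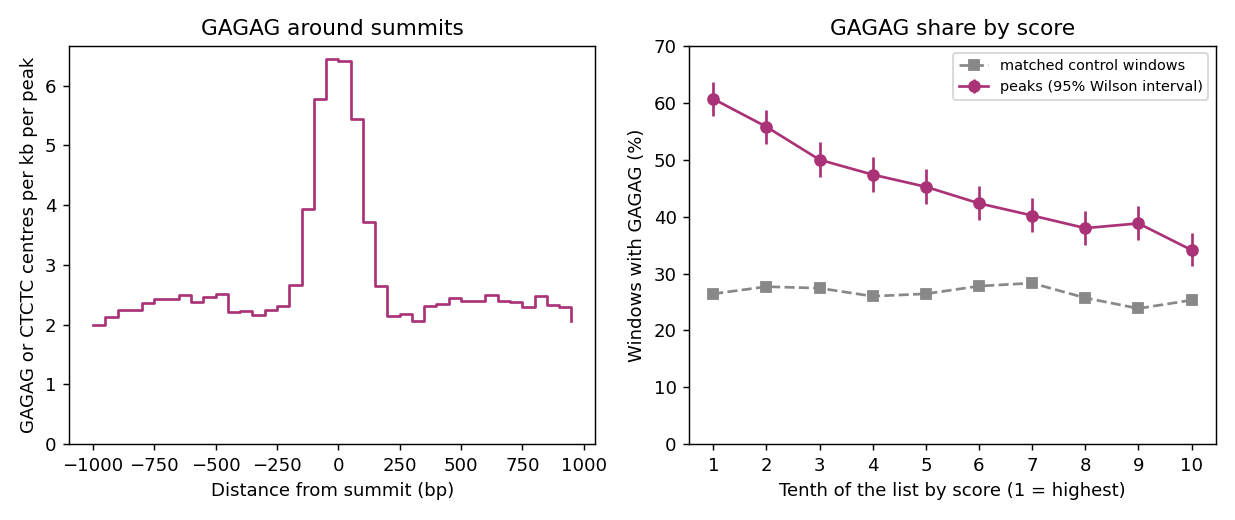
Left, occurrences of GAGAG or its complement per kb and peak (y axis) by distance from the summit in bp (x axis, bins of 50 bp), with a maximum of 6.44. Right, percent of summits with GAGAG within 100 bp (y axis) in 10 equal parts of the list by score (x axis), with 95% Wilson intervals over peaks; peaks fall from 60.7% to 34.1% and controls stay between 23.9% and 28.3%.

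Some other sequences known from fly promoters were above matched windows too. The windows were not matched on distance to a TSS, so an effect of summit position near TSSs is not separated for core promoter words. TATCGATA, the site of the DREF factor, was found at 2.89% of summits against 0.584% (odds ratio 5.07, adjusted p = 2.34e-38, Fisher's exact test), and GGTCACAC, part of a core promoter element of housekeeping genes, at 2.65% against 0.91% (odds ratio 2.97, adjusted p = 3.78e-21). With 250 bp on each side, the odds ratio of TATCGATA was 2.0 (4.25% against 2.17%). CACACACA (14.7% against 5.89%, odds ratio 2.75), AACCGGTT (1.02% against 0.247%, 4.15) and CGATA (26.3% against 21.2%, 1.32) were above controls as well, with adjusted p of 6.48e-96, 2.03e-12 and 3.83e-17 by Fisher's exact test. AAAAAAAA was above matched windows (10.4% against 6.94%, odds ratio 1.56, adjusted p = 2.71e-18, Fisher's exact test) but below windows 1000 bp away (odds ratio 0.823). GCCAT, the core of the Pho site, was below controls (32.2% against 39.9%, odds ratio 0.717, adjusted p = 2.02e-29, Fisher's exact test), a difference that ended against windows 1000 bp away (0.978). The E-box CACGTG was slightly below matched windows (odds ratio 0.814, adjusted p = 0.0153, Fisher's exact test). This call ended against windows 1000 bp away (1.14, adjusted p = 0.157, Fisher's exact test) and with 50 bp (0.907) or 250 bp (0.98) on each side. It also ended in the higher-scoring part of the list (0.82, 5052 peaks) and without replicate 1 (0.813, 6832 peaks). In these 2 the odds ratio was about the same, with fewer peaks. CAGGTAG, the site of the early activator Zelda, did not pass the test (1.71% against 1.43%, adjusted p = 0.127, Fisher's exact test), but passed against windows 1000 bp away (odds ratio 1.3) and without replicate 2 (1.42).

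Of 13968 protein-coding genes, 4003 (28.7%) had a summit within 1000 bp of a TSS, and 12 of 29 gene lists were bound more often than matched random lists while 4 were bound less often. Genes for BTB or Psq-domain factors and ecdysone response genes had the highest shares bound. Of 24 ecdysone response genes 22 were bound against 13.6 expected (adjusted p = 0.00145, permutation; 90.3% ± 2.41 over the replicates, SD, n = 3). Besides EcR, crol and Hr3 they included the nuclear receptor gene Hr39 (relative score 5.09 ± 2.03, SD, n = 3), while ImpL1 and Hr38 had no such peak. Of 18 genes for BTB or Psq-domain transcription factors 17 were bound against 10.2 expected (adjusted p = 0.00145, permutation). These included psq, ken (3.7 ± 0.555), chinmo (3.18 ± 0.626) and lola, whose promoter peak varied between replicates (3.98 ± 2.84, SD, n = 3), and rib was the exception. Without matching on length and TSSs, the ratio of bound to expected was 3.2 for ecdysone response genes (1.62 with it) and 3.28 for BTB or Psq-domain genes (1.67). The smallest unadjusted p that the 10000 draws of the list tests can give is 0.0002.

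Genes of Polycomb silencing and many of its known targets were bound. Of 22 Polycomb group genes 15 had a peak against 8.12 expected (adjusted p = 0.0058, permutation). The strongest were Psc (6.8 ± 1.62), ph-d (6.38 ± 0.731), ph-p (5.97 ± 1.82) and Su(z)2 (5.08 ± 0.679; SD, n = 3 each), which encode subunits of Polycomb repressive complexes. The adjacent ph-d and ph-p are near-identical copies, so the division of reads between them is uncertain. Of 56 developmental regulators repressed by Polycomb 40 were bound against 23.4 expected (adjusted p = 0.00116, permutation), among them wg (2.51 ± 0.464), Dr (2.31 ± 0.471), Dll (2.33 ± 0.552) and dac (2.38 ± 0.913; SD, n = 3 each), at lower relative scores than the Polycomb genes named. Trithorax group genes, which counter this silencing, did not differ from matched lists (9 of 19 against 8.59, adjusted p = 1.00, permutation). The highest near their TSSs were mor (6.99 ± 0.789) and kis (6.56 ± 1.19; SD, n = 3 each), that of mor being nearer to Hel89B. Without matching their ratio rose from 1.05 to 1.64 (adjusted p = 0.189, permutation). Of the 8 homeotic genes 4 were bound against 4.55 expected (adjusted p = 1.00, permutation). Peaks near TSSs of lab (1.87 ± 1.03), Abd-B (1.13 ± 0.376), Scr (0.795 ± 0.138) and Antp (0.647 ± 0.169) were modest (SD, n = 3 each). The homeotic ratio of 0.878 turned to 1.74 without matching (adjusted p = 0.388, permutation). With 1000 bp added on each side, the span of Antp held 15 optimal peaks and that of Ubx 2, the higher of which lay next to modSP. The spans of pb, Dfd and abd-A held none. By the highest-scoring peaks of single replicates, Dfd was bound in replicate 1 and pb in replicate 3.

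Signalling and growth genes were bound above matched lists in several pathways. This held for the Notch (15 of 19 against 6.67, adjusted p = 0.00116), Dpp and activin (18 of 21 against 9.25, 0.00145), EGFR (16 of 20 against 9.03, 0.00657) and Hippo pathways (13 of 16 against 6.77, 0.0058) and for cell cycle genes (16 of 23 against 8.98, 0.00532; all by permutation). Examples were the receptor gene N (5.67 ± 0.987), the protease gene kuz (4.97 ± 0.501), mam (3.65 ± 0.685) and neur (3.4 ± 1.31) in the Notch pathway, and wit (4.998 ± 0.819), brk (4.58 ± 1.05), shn (4.36 ± 0.837) and Med (3.89 ± 1.04) in the Dpp pathway (SD, n = 3 each). The EGFR list was led by the ETS repressor gene aop (4.04 ± 0.593), with the ligand genes spi (3.38 ± 0.393) and Krn (2.96 ± 0.682) and the inhibitor gene aos (2.39 ± 0.671; SD, n = 3 each). Hippo genes were led by ex (4.41 ± 0.335), yki (3.49 ± 1.01), hpo (3.42 ± 0.791) and sd (2.95 ± 0.607), and cell cycle genes by the inhibitor gene dap (6.43 ± 0.856), Dp (3.92 ± 0.784), stg (3.83 ± 0.098) and E2f2 (3.13 ± 0.524; SD, n = 3 each). The peaks counted for kuz and yki lay nearest to B4 and Gpat4. The cell cycle call ended without replicate 3 (adjusted p = 0.0555, permutation), and without matching the ratio rose from 1.95 to 2.99 for Dpp and from 1.77 to 2.79 for EGFR genes. Wnt (15 of 22 against 10.1, adjusted p = 0.0751; fz2 3.54 ± 0.479, Notum 3.23 ± 0.37), Hedgehog (9 of 15 against 6.52, 0.355; ptc 2.8 ± 0.917, dlp 2.23 ± 0.394) and cell death genes (7 of 13 against 3.81, 0.129; hid 4.17 ± 0.744, Dcp-1 3.43 ± 0.783) did not pass the permutation test (SD, n = 3 each). The peak of Dcp-1 is also the promoter peak of pita. Each of these 3 lists passed under some alternatives, as Wnt genes did without replicate 3 (adjusted p = 0.0352), cell death genes without replicate 1 (0.0323) and Hedgehog genes without matching (0.0383; all by permutation).

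Ribosomal protein genes, cytoplasmic and mitochondrial, and heat shock genes were bound more often than matched genes. Of 85 cytoplasmic ribosomal protein genes 61 were bound against 23.8 expected (adjusted p = 0.00116, permutation; 74.1% ± 2.04 over the replicates, SD, n = 3). Their strongest promoter peaks were at RpS27 (4.56 ± 0.977), RpL7 (4.27 ± 0.285), RpL28 (3.6 ± 0.339) and RpL41 (3.46 ± 0.385; SD, n = 3 each). Mitochondrial ribosomal protein genes followed with 26 of 73 against 11.2 (adjusted p = 0.00116, permutation), led by mRpS21 (5.53 ± 0.227), mRpL33 (4.48 ± 0.465), mRpL43 (3.35 ± 1.15) and mRpL53 (3.27 ± 0.111; SD, n = 3 each), at each of which the peak lay nearest to a neighbouring gene. Without matching on length and TSSs their ratio fell from 2.31 to 1.24 (adjusted p = 0.31, permutation). Of 21 heat shock genes 14 were bound against 6.29 (adjusted p = 0.00316, permutation), led by Hsp83 (4.997 ± 0.51), Hsp27 (4.54 ± 0.134), Hsp23 (3.46 ± 1.54) and Hsp26 (2.75 ± 0.437; SD, n = 3 each).

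Chemosensory receptor, neuronal, muscle and blood cell genes were bound less often than matched genes. The chromatin came from whole larvae, so binding limited to few cells may be without a call. Only 3 of 119 olfactory and gustatory receptor genes had a peak, against 23.1 expected (adjusted p = 0.00116, permutation). Of these, Or67a (0.822 ± 0.605) was the nearest gene, while the peaks counted for Gr63a (1.33 ± 0.717) and Gr97a (0.871 ± 0.251) lay nearer to Lamtor4 and CG5521 (SD, n = 3 each). Of 20 neuronal genes 3 were bound against 11.4 (adjusted p = 0.00193) and of 20 muscle genes 3 against 9.94 (adjusted p = 0.0029, both by permutation). The bound members were Syx1A (9.12 ± 0.955), elav (3.86 ± 0.814) and futsch (0.616 ± 0.283) in the neuronal list, and Zasp52 (3.73 ± 0.736), Tm1 (2.35 ± 0.313) and Mef2 (1.45 ± 0.26) in the muscle list (SD, n = 3 each). Without matching, the neuronal and muscle calls ended (ratios 0.523 and 0.522, adjusted p = 0.318 for each, permutation), and the muscle call also ended in the higher-scoring part of the list (adjusted p = 0.0718, permutation). Blood cell genes had 2 of 15 against 6.42 (adjusted p = 0.0268, permutation), a call that ended under each of the 7 alternatives. The 2 bound members were the GATA factor gene srp (4.1 ± 0.759) and its partner ush (7.83 ± 1.12; SD, n = 3 each).

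The remaining lists did not differ from matched genes by the permutation test. Insulator and architectural protein genes had 7 of 14 bound against 4.63 (adjusted p = 0.348; pita 3.43 ± 0.783, Dref 2.73 ± 0.587 at a peak nearest to RpL13), and passed in the higher-scoring part of the list (adjusted p = 0.0297, permutation). Juvenile hormone pathway genes had 7 of 12 against 4.36 (0.225; Kr-h1 2.88 ± 0.209, Jheh1 2.02 ± 0.915), and ecdysteroid biosynthesis genes 4 of 13 against 4.53 (1.00; mld 6.81 ± 0.99, shd 0.977 ± 0.161; SD, n = 3 each). Salivary glue genes had 2 of 11 against 1.41 (0.968), a single peak shared by the adjacent Sgs5 and Sgs5bis (0.941 ± 0.415), and fat body storage and yolk genes 2 of 11 against 3.76 (0.522; Apoltp 1.99 ± 0.408, Fbp1 0.659 ± 0.2; SD, n = 3 each). Antimicrobial peptide genes had 1 of 14 against 1.51 (1.00), a peak in an intron of magu, 964 bp from the TSS of Def (1.37 ± 0.61, SD, n = 3). Larval and pupal cuticle genes had 0 of 24 against 3.31 (0.0815) and chorion genes 0 of 9 against 1.35 (0.56). Cuticle genes passed when a summit anywhere in the span counted (adjusted p = 0.0464) and without matching (0.00166, both by permutation).

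**Figure D5:**
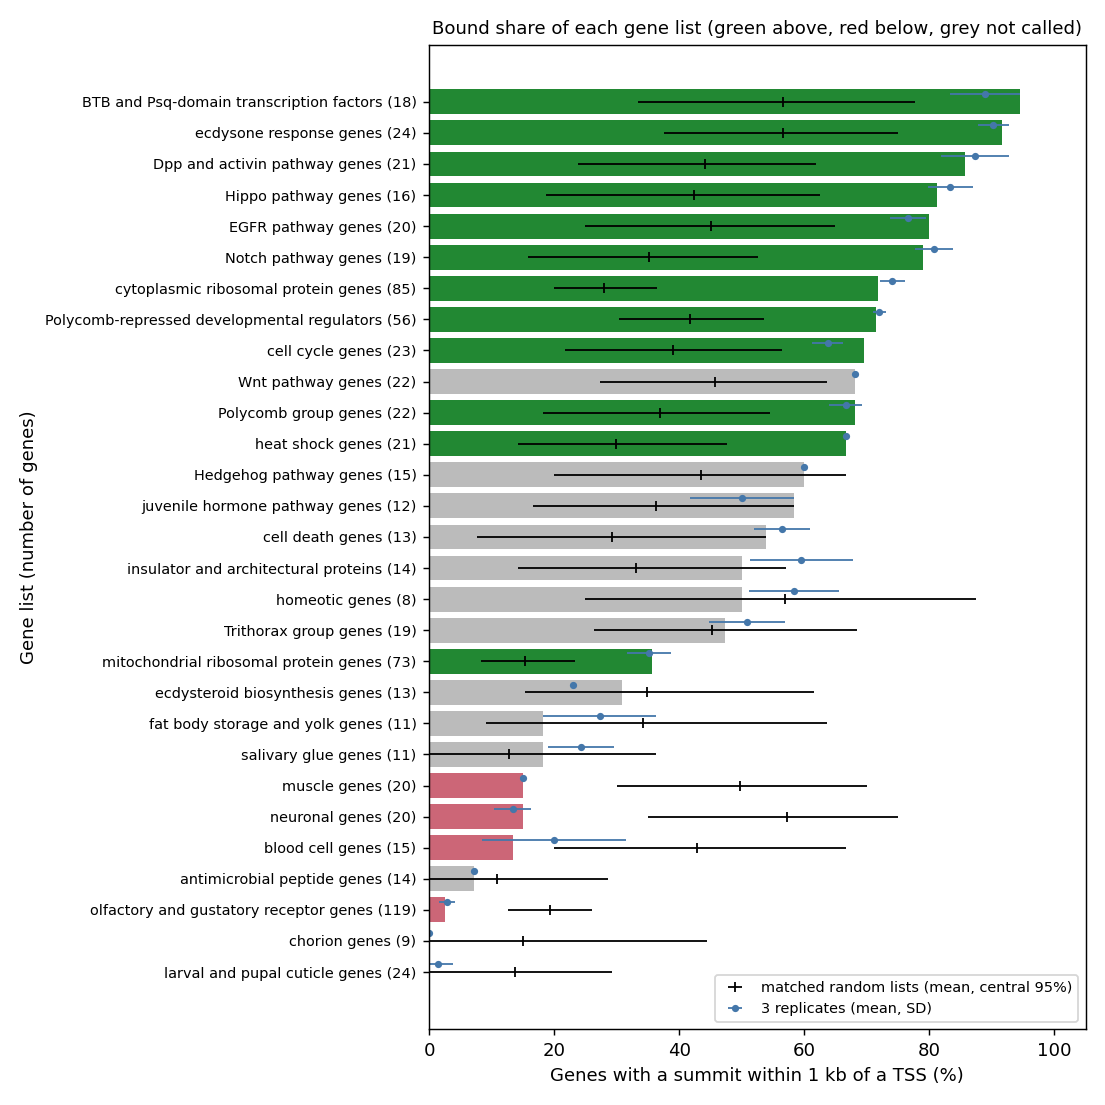
Percent of genes of each list (y axis, with the number of genes) with a summit within 1 kb of a TSS (x axis), with bars for the optimal list (green above and red below in the permutation test), black lines for the mean and central 95% of matched random lists and blue points for the mean and SD of the 3 replicates. Ecdysone response genes reached 91.7% and olfactory and gustatory receptor genes 2.52%.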

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

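The test between genome builds was chosen after the result was seen, and the test of GA sites was not.

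The list of optimal peaks held 33 peaks in mitochondrial DNA, which the comparisons of nuclear sites leave out. The highest had a score of 23557, which is 3.15 times that of the highest nuclear peak, and the highest nuclear peak ranked at place 19 of the list. With the same libraries on the older build dm3, the optimal list held 9 mitochondrial peaks and the highest had a score of 2749, or 0.367 times the highest nuclear score. The highest nuclear score was almost the same in both builds (ratio 0.999). Over the replicates the ratio of highest mitochondrial to highest nuclear score was 3.12 ± 0.586 on dm6 and 0.457 ± 0.131 on dm3 (SD, n = 3), and the fold between builds was 6.95 ± 0.702 (SD, n = 3). A candidate explanation is therefore a difference between the builds. It may lie in a step of the processing, such as how reads or the control were assigned to mitochondrial DNA, or in the assemblies themselves. The dm3 optimal list also held 17 peaks on Uextra, 2 on U and 1 on 3LHet, and the dm6 list held none on these sequences. Which difference it was cannot be read from peak lists. Binding at GA sites in mitochondrial DNA stays open for want of sites: GAGAG lay near 1 of 32 testable mitochondrial summits (3.12%), against 1.02% of random mitochondrial positions (p = 0.276, 10000 draws, permutation). No biological explanation was tested beyond this, since the design has a single group.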

How the results depend on the processing

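The alternatives that leave out a replicate in the overlap between replicates were added after seeing the data; all others were fixed before. Overlap between replicates stayed above random draws in all 7 alternatives (62.1% to 78.1%), promoters above random placement in 6 (ratio 2.39 to 5.52), GAGAG above controls in 7 (odds ratio 1.92 to 2.9), TATCGATA above controls in 7 (2.0 to 5.66), and the X to autosome ratio near 1 in 4 (0.97 to 1.03). On dm3 the optimal list held 9886 peaks. The number of lists bound above matched lists was 12 to 15. Support of optimal peaks by all replicates was 58.4%, and it was 49.2% with summits within 100 bp, 67.3% within 500 bp and 85.6% against the full lists, as wider distances and longer lists give by construction. It was 65.3% to 67.7% without a replicate, where only 2 needed to match. The coding sequence ratio, 0.0664, was 0.0318 in the higher-scoring part of the list and 0.0419 to 0.0499 with each replicate left out in turn. The intron ratio turned to 1.03 with promoters of 200 bp, which by construction moves observed and placed summits 200 to 500 bp from a TSS into other classes. Against windows 1000 bp away, AAAAAAAA turned to an odds ratio of 0.823 and CACGTG to 1.14, which did not pass; the cause was not tested. For lists, values are ratios of bound to expected. In the higher-scoring part of the optimal list, with fewer bound genes, 2 lists were below (4 in the main analysis), muscle (0.414) and blood cell genes (0.438) no longer passed, and insulator (2.48), Wnt (1.8) and cell death genes (2.97) passed. Within 500 bp of a TSS blood cell genes (0.34) did not pass. With the whole span counted, blood cell genes (0.417) did not pass and cuticle genes (0) did. Without matching, 2 lists were below, mitochondrial ribosomal protein (1.24), neuronal (0.523), muscle (0.522) and blood cell genes (0.466) no longer passed, and cuticle (0), Wnt (2.37) and Hedgehog genes (2.11) passed. There the ratio also rose for BTB or Psq-domain (1.67 to 3.28), ecdysone response (1.62 to 3.2), Dpp (1.95 to 2.99) and EGFR genes (1.77 to 2.79), which passed with and without matching, and for homeotic (0.878 to 1.74) and Trithorax group genes (1.05 to 1.64), which passed in neither. Muscle genes rose from 0.302 to 0.464 with the whole span counted and still passed. Among other lists that did not pass, ratios of salivary glue (0.633 to 2.52), antimicrobial peptide (0 to 1.16), fat body (0.286 to 1.15) and ecdysteroid biosynthesis genes (0.573 to 1.07) also fell on both sides of 1. Without a replicate, blood cell genes (0.383 to 0.393) did not pass, cell cycle genes (1.73 to 2.0) did not without replicate 3, and cell death genes (2.1 to 2.44) passed without replicate 1 and Wnt genes (1.47 to 1.7) without replicate 3. The causes of these changes were not tested. No paired analysis was possible because the series has 1 group only. Depth is unknown and the chromatin came from whole larvae. Genes and lists given as bound less often or without a peak are therefore only without a call in these lists. Binding below the reach of the peak calls, or limited to few cells, is not excluded.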

Other observations

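The comparison of GAGAG between lists, the search for repeated sequence at psq, the ratio of highest to median score at psq, the comparison with proteasome and synthetase genes alone and the count of genes with many peaks in each list were chosen after the results were seen, and so were the genes named for their number of peaks and the search over all words of 6 bases.

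Some long genes were covered by many peaks. The span of sbb (2R:18278198-18357296) held 47 optimal summits, that of Eip75B (3L:17950953-18064696) 44, psq 43 and jing (2R:6502006-6621792) 41. The next were Mur2B and Tet with 38 each, CG1677 35, Tlk 34, E2f1 33, EcR and tara 32 each, shn 31 and brat 30. Per length, tara was the densest of these, with 0.923 summits per kb. Of 69 genes with at least 15 summits, 6 were ecdysone response genes (Eip75B, EcR, br, Eip74EF, tai and Hr4). Lists of other genes drawn from the 50 nearest in length to each member held 0.998 such genes on average, a ratio of 6.01 (adjusted p = 0.0058 over 29 lists, 2-sided permutation, 10000 draws). EGFR pathway genes (Egfr, Raf, pnt and aop, 4 against 0.28, adjusted p = 0.0058) and Trithorax group genes (osa, kis and skd, 3 against 0.197, 0.00967) passed the same permutation test, and no other list did. Genes of these 3 lists may carry more sites than their length gives, and since the ecdysone genes were first noticed in these data, this is a hypothesis. Overlapping spans were counted for each gene, and sites within a gene are not independent.

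Within 500 bp of a TSS a summit was found for 51 of 290 transfer RNA genes (17.6%), 6 of 32 small nuclear RNA genes (18.8%), 30 of 269 small nucleolar RNA genes (11.2%), 468 of 3289 other non-coding genes (14.2%), 12 of 330 pseudogenes (3.64%), 0 of 99 ribosomal RNA genes and 3581 of 13968 protein-coding genes (25.6%). Differences between these kinds of gene were not tested. Of 2080 words of 6 bases, 475 were more and 965 less frequent at summits than in matched windows (adjusted p under 0.05, Fisher's exact test). AGAGAG had the lowest p (26.3% against 9.25%, odds ratio 3.5), and ACACAC was found at 27.8% against 15.1% (odds ratio 2.17). Among the less frequent words CCAGGA had the lowest p (3.88% against 11.8%, odds ratio 0.302).

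The GA word was unevenly spread over the bound gene groups. Near the TSSs of developmental regulators repressed by Polycomb, 43 of 56 peaks (76.8%) had GAGAG, against 46.2% of the other peaks near protein-coding TSSs (odds ratio 3.85, adjusted p = 5.32e-05, Fisher's exact test over 22 lists with at least 5 peaks). Ecdysone response genes (65.6%, adjusted p = 0.021) and EGFR pathway genes (68.3%, 0.0376) were also above by Fisher's exact test. Cytoplasmic ribosomal protein genes were the opposite, with 8 of 78 peaks (10.3% against 47.1%, odds ratio 0.129, adjusted p = 1.41e-10, Fisher's exact test). The remaining lists did not pass, among them mitochondrial ribosomal protein genes with 9 of 34 peaks (26.5%, adjusted p = 0.104, Fisher's exact test).

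If signal at any promoter used in all cells explained the binding of cytoplasmic ribosomal protein promoters without GAGAG, other such groups would be bound as often. Proteasome (11 of 32), respiratory chain (28 of 86), vacuolar ATPase (8 of 33), translation factor (21 of 52) and aminoacyl-tRNA synthetase genes (6 of 17) were bound at 33.6% together, against 71.8% of cytoplasmic ribosomal protein genes (p = 1.96e-09, Fisher's exact test), and none of the 5 groups passed the matched test (lowest adjusted p = 0.277, permutation). Respiratory chain, vacuolar ATPase and translation factor genes include copies such as COX4L, Vha100-3 and eIF4E3 that need not be used in all cells and lower this share, but proteasome and synthetase genes alone were at 34.7% (17 of 49, p = 4.99e-05, Fisher's exact test), which argues against this as the whole cause of how often ribosomal protein genes were bound. GAGAG was found at 2 of 13 proteasome peaks (15.4%), 1 of 10 synthetase peaks, 10 of 37 respiratory chain peaks (27.0%), 14 of 38 translation factor peaks (36.8%) and 9 of 17 vacuolar ATPase peaks (52.9%), differences that were not tested, and signal that scales with transcription stays open, since expression was not measured here. With 500 bp on each side 64.1% of the ribosomal peaks had GAGAG against 81.0% of the others (p = 0.000441, Fisher's exact test). The odds ratio was 0.418 there and 0.129 within 100 bp. The wider window holds the inner one and thus its known difference, so a GA site farther off stays open.

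Promoter peaks may be of more than 1 sequence kind. TATCGATA or GGTCACAC was found at 15.6% of promoter peaks without GAGAG and 5.48% of those with it (odds ratio 3.2, p = 2.03e-28, Fisher's exact test), and at 31 of 78 ribosomal peaks (39.7%). AACCGGTT did not pass (0.644% without against 0.659% with, odds ratio 0.976, p = 1, Fisher's exact test), and CACACACA went the other way (10.8% without against 17.3% with, odds ratio 0.578). A candidate explanation is that part of the promoter peaks depend on factors at these elements and not on GA repeats. Promoters without a peak were not compared, so a split that promoters share whether bound or not is not excluded.

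The strongest nuclear peak lies in the gene that carries the tag, and the flies were transgenic per the labels. Extra DNA copies of that region in the tagged line were therefore weighed. All 72 peaks of the list called on the replicates together within the psq span had a median score of 141. This was at percentile 96.2 of the medians of 598 other genes with at least 10 peaks, as a raised signal over the region would give. Dense binding would give it too, and psq was picked for its highest peak, so this percentile does not decide between them. The lower quartile of their scores (38.2) was at percentile 83.1. Extra copies could raise weak peaks but also lift weaker sites into the list, so this quartile does not decide on them. The highest peak was 53.1 times the span median, but psq was picked for that peak, so this ratio decides nothing on extra copies. Repeated sequence is argued against, as 0% of the words of 31 bases at the summit occur more than once in the genome. Dense binding of Psq at its own gene stays open beside extra copies, and the number of copies in these flies was not analysed here.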
